A study of Mus musculus with 64 samples.

How the data were processed

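RNA from striatum and cortex of 32 mice was measured in 64 libraries prepared from total RNA with a TruSeq stranded kit after Qiagen RNeasy extraction, per the labels' protocols. Reads were aligned with STAR 2.7.5c, handled with SAMtools 1.10 and counted per gene with HTSeq 0.12.3 on the GRCm38 (mm10) build, per the submitters' processing notes. The strand setting of the counting is not given in the sources used here. The authors deposited raw gene counts and FPKM values for each library, and both hold 48795 genes. The deposited FPKM values were found to be the counts rescaled by gene length and library total, with no further normalization between libraries: over 15456 genes with 10 or more counts in every library, the ratio of count to FPKM divided by the library total had a relative spread of 3.3e-08. The tables had 0 columns of other samples. Gene positions and types came from a GRCm38 annotation that held 48349 of the gene IDs, and 27 gene names that a spreadsheet had turned into dates were replaced by the annotation's names.

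Groups, sex and replicate names were taken from the labels. Total gene counts per library were 28.7 to 40.6 M in striatum and 30.9 to 40.1 M in cortex. Within a genotype the log2 CPM of libraries correlated at r = 0.9859 or more in striatum and 0.9913 or more in cortex. Levels of sex-linked genes matched the labelled sex in all 64 libraries, and no 2 libraries agreed within sampling noise. After group means were removed, same-numbered mice correlated little in the median. Replicate numbers were therefore not used in the fits reported, except that both tissues of a mouse share the mouse.

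Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust estimation, TMM scaling, the default low-count filter by genotype, sex as a covariate). All 32 libraries of a tissue entered 1 fit, and comparisons were contrasts. The filter left 18270 genes in striatum and 18116 in cortex. P-values were adjusted by Benjamini and Hochberg over the genes tested in each comparison and called under 0.05. The interaction was the Q140 effect in mice labelled Polq+/- minus that in mice with both copies. The difference between tissues was fitted over all 64 libraries with the mouse as a block, and the difference between sexes over 8 cells of genotype and sex. Log2 fold changes are edgeR's, CPM are TMM-scaled, and the number of mice beyond the other group's median counts the direction of a change. That count was first made against the mean and was changed to the median after 1 library was seen to set the mean of Cbln3 and Cbln1.

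The genes named were set by a rule: Polq and Htt in every comparison; among genes with adjusted p under 0.05 and a mean CPM of at least 1, the 10 largest rises and 10 largest falls, or all when 20 or fewer passed, leaving out predicted genes without an assigned name only when more than 20 passed; and up to 4 members of a gene list with the smallest p. The 29 gene lists covered spiny neuron, other neuronal, glial, vascular, blood and choroid plexus markers, thalamic and cortical markers, immediate early and circadian genes, developmental transcription factors, protocadherins, cholesterol synthesis, heat shock, DNA repair, p53 targets, respiratory chain genes (nuclear and mitochondrial), ribosomal proteins and interferon response. Each needed at least 3 tested members and was tested with camera in limma 3.58.1 on log2 CPM (prior count 3, preset correlation 0.01), again with an estimated correlation, and with fry. Camera asks whether a list stands apart from other genes, fry's first p whether its genes move on balance in 1 direction, and fry's mixed p whether they change in either. The signature score used the 200 genes with the smallest p for Q140 against wild type in 1 sex (4 against 4 mice) to score the mice of the other sex as the mean of signed log2 CPM relative to the wild types of that sex. Differences were tested by exact two-sided permutation of genotypes within sex (4900 arrangements, smallest p 0.00041) with intervals (95%) from 10000 bootstrap draws of mice. Neighbours of the targeted genes were counted within 10 Mb and tested with Fisher's exact test.

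These designs, lists, the naming rule and the following alternatives were fixed before the data were examined: DESeq2 size factors in edgeR, DESeq2 1.42.0, limma voom, limma trend on deposited FPKM with a pseudocount of 0.1 or 1, no low-count filter, only the groups compared, no sex term, the replicate number as a block, the plate column, a first surrogate variable (sva 3.50.0), a dissection covariate, a random block by mouse-name prefix, an adjusted p under 0.1, scores of 100 and 500 genes, and leaving out each library in turn. Leaving out the 4 mice of low Polq, and leaving out 3 striatal libraries that stood apart (wild-type male 2 and male 3, Polq+/- female 3), were chosen after seeing the data, as were gene lists without wild-type male 3, the cortical concordance without Gm2420 and the test of the whole of chromosome 16. Other splits of the mice into groups of the same sizes numbered 100 per result, the real one included, and 24 for the difference between tissues.

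The steps were tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each size. Each gene was drawn on its own, and far fewer genes were changed than the 5869 called for Q140 in striatum. Recovery and false calls in the real comparisons may therefore differ. The gene tests of the interaction and of the Polq label were not simulated. For Q140 against wild type in striatum (18186 genes) the fit recovered 50%, 76%, 94% and 98% of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, with 5.36% of calls false. In cortex (18013 genes) it recovered 44%, 80%, 92% and 100%, with 1.86% false. For the difference between tissues (18982 genes) it recovered 42%, 70%, 88% and 94%, with 6.96% false, for the difference between sexes in striatum (18191 genes) 16%, 54%, 80% and 94%, with 1.61% false, and in cortex (17999 genes) 20%, 60%, 78% and 98%, with 0.775% false. Intervals of counts are not given for single libraries because the spread between mice exceeds counting error, and low counts such as those of Polq are given beside their CPM.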

Results

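Striatum and cerebral cortex were profiled by RNA sequencing in 32 C57BL/6 mice aged 6 months. The Q140 allele is a knock-in of an expanded CAG tract into the mouse huntingtin gene (Htt) and models Huntington's disease, in which the spiny projection neurons of the striatum are the cells most affected. Polq encodes DNA polymerase theta, which joins broken DNA ends. The labels gave 4 genotypes: wild type, Polq+/-, Q140 and Q140 Polq+/-. They gave the Q140 knock-in as heterozygous in both Q140 groups. Each genotype had 8 mice (4 females and 4 males), with 1 library per tissue from every mouse, 64 libraries in all. The replicates were therefore separate animals. Total gene counts per library ran from 28.7 to 40.6 M in striatum (median 34.7 M) and from 30.9 to 40.1 M in cortex (median 34.5 M).

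The targeted genes were examined first. Polq (ENSMUSG00000034206, plus strand of chromosome 16, 37011786 to 37095417 on GRCm38) had a mean of 3.14 ± 0.506 CPM (counts scaled to library size; SD, n = 8) in wild-type striatum and 3.10 ± 0.409 in Q140 striatum. It stood at 1.66 ± 0.647 CPM in mice labelled Polq+/- and at 1.35 ± 0.939 in mice labelled Q140 Polq+/-. In cortex the means were 2.48 ± 0.52, 2.39 ± 0.374, 1.19 ± 0.245 and 1.09 ± 0.606 CPM for wild type, Q140, Polq+/- and Q140 Polq+/-. Raw Polq counts were small, between 6 and 148 per striatal library. The lower level passed edgeR's test adjusted over all genes in cortex of mice labelled Q140 Polq+/- against Q140 (log2 fold change -1.14, SE 0.226, adjusted p = 0.0394, 8 of 8 mice below the Q140 median). It did not pass in cortex of mice labelled Polq+/- against wild type (-1.06, SE 0.223, adjusted p = 0.0797, 8 of 8), in striatum of the same mice (-0.90, SE 0.321, adjusted p = 0.938, 8 of 8) or in striatum of Q140 Polq+/- against Q140 (-1.18, SE 0.33, adjusted p = 0.926). The spread within the groups was wide: 4 of the 16 mice labelled Polq+/- (male 3 of Polq+/-, and female 3, female 4 and male 3 of Q140 Polq+/-) lay at 0.187 to 0.376 CPM in striatum and 0.375 to 0.602 CPM in cortex. The other 12 lay at 1.31 to 2.42 CPM and 1.12 to 1.93 CPM. These 4 mice had the lowest Polq of the 16 in both tissues, a level lower than the label of 1 intact copy gives in the other 12. The labels were kept, the groups are called "mice labelled Polq+/-" throughout, and every direction drawn from them below carries that doubt. Htt (ENSMUSG00000029104, plus strand of chromosome 5, 34761740 to 34912534) was not called in any comparison with all libraries, with 204.9 ± 27.8 CPM in wild-type and 197.6 ± 5.92 CPM in Q140 striatum (log2 fold change -0.05, SE 0.0558, adjusted p = 0.534, 8 of 8 mice below the wild-type median). The wild-type mean was lowered by male 3, at 137 CPM against 209 to 220 in the others. Without that library Htt was called lower in Q140 against wild type (-0.118, SE 0.0248, adjusted p = 0.000256) and in Q140 Polq+/- against Polq+/- (-0.107, SE 0.0239, adjusted p = 0.000464; -0.113, SE 0.0558, adjusted p = 0.126 with all libraries). In cortex it was 232.0 ± 5.47 and 218.7 ± 13.2 CPM (-0.09, SE 0.0342, adjusted p = 0.355, 7 of 8).

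**Figure D1:**
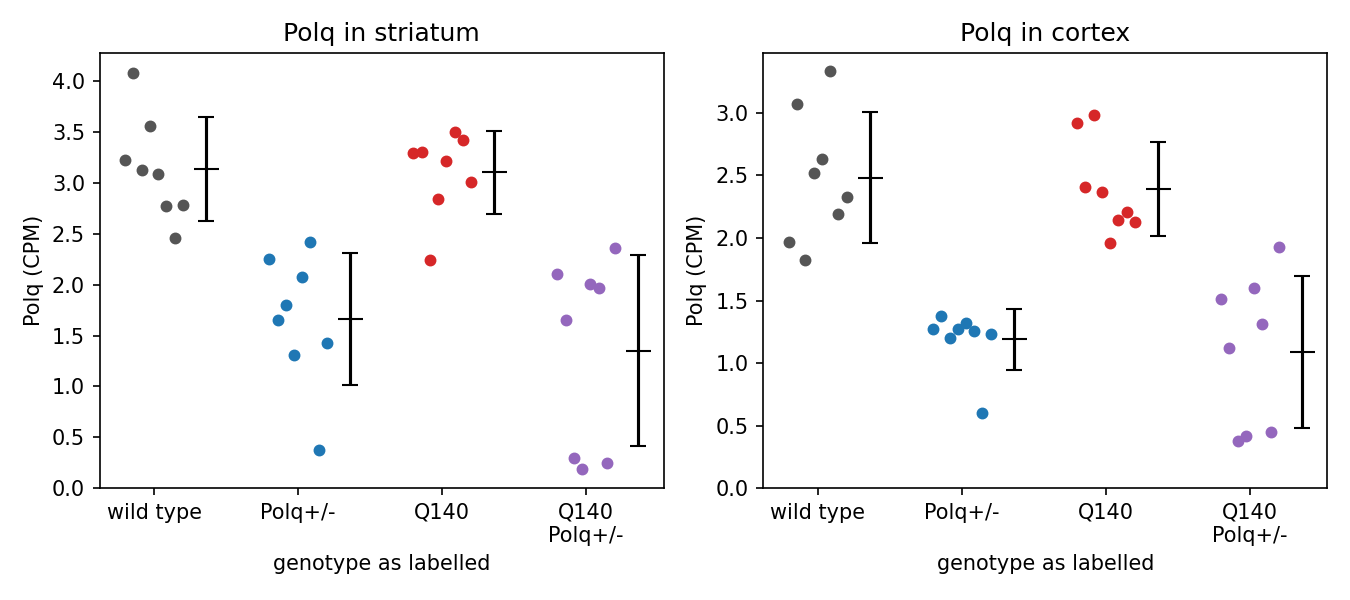
Polq level (CPM, y axis) in each mouse by labelled genotype (x axis), for striatum and cortex. Points are mice and the bar is the mean ± SD (n = 8 per genotype); 4 mice labelled Polq+/- lie at 0.187 to 0.376 CPM in striatum and 0.375 to 0.602 CPM in cortex.

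The comparison of Q140 with wild type asked what the expanded allele changed in striatum when both Polq copies were present. Spiny projection neuron genes fell together. All 26 tested genes of a list of markers shared by both spiny neuron types fell, among them Scn4b (a sodium channel beta subunit, log2 fold change -1.17), Arpp21 (a cAMP-regulated phosphoprotein, -0.82), Pde1b (a phosphodiesterase, -0.65) and Ppp1r1b (DARPP-32, the dopamine-regulated phosphatase inhibitor, -0.65). All 24 genes of a list reported as reduced in Huntington's disease models also fell, a list that overlaps the first. Markers of the indirect pathway fell in 4 of 6 tested genes: the enkephalin precursor Penk (-1.21), the adenosine receptor Adora2a (-0.88), the receptor Gpr6 (-0.65) and the dopamine receptor Drd2 (-0.61). Adjusted over the list alone the indirect pathway list had 4 falls and 1 rise, and the 2 larger lists kept all 26 and 24 falls. The lists stood below the rest of the genome by camera with its preset correlation (adjusted p = 1.52e-33, 5.65e-38 and 1.35e-05), and with an estimated correlation their adjusted p were 0.0128, 0.00131 and 0.0385. Without wild-type male 3 the indirect pathway list was at adjusted p = 0.0563 with an estimated correlation, past the threshold (0.0393 without the 3 libraries that stood apart), and the other 2 at 0.0114 and 0.00301. Direct pathway markers went both ways, 5 down (Drd1 at -0.60 and Chrm4 at -0.54 among them) and 2 up (the transcription factors Isl1 at 0.34 and Eya1 at 0.40) of 9 tested, the same adjusted over the list alone. On FPKM 4 were down and 4 up, and the list did not stand apart (camera adjusted p = 0.261).

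In all, 5869 of 18270 tested genes (32.1%) passed in striatum of Q140 mice, 3095 higher and 2774 lower, against 7459 at an unadjusted p under 0.05. Of these, 54 rose and 117 fell by more than 2-fold. The gene with the smallest adjusted p was Ddit4l, an inhibitor of mTOR signalling (-2.16, SE 0.0713, adjusted p = 9.34e-22), which went from 40.2 ± 4.67 to 9.02 ± 0.75 CPM with 8 of 8 Q140 mice below the wild-type median. Large falls also met the glutathione peroxidase Gpx6 (-2.62, SE 0.122; 12.9 to 2.06 CPM), the Wnt ligand Wnt8b (-2.81), the transcription factor Mafa (-2.39), the lipid-binding protein Sec14l3 (-2.23), the calcium-binding copine Cpne9 (-2.02), Dgat2l6 (-1.96) and Abhd11os (-1.87). Abhd11os lies antisense to Abhd11, and the strand setting of the counting is not given in the sources used here, so its reads cannot be assigned with certainty. Among genes with an assigned name and a mean of at least 1 CPM, the largest rise was that of Sfmbt2, a Polycomb group gene (2.01, SE 0.107; 2.38 ± 0.587 to 9.52 ± 0.985 CPM, 8 of 8). Dsp (desmoplakin, 1.82), Ttn (titin, 1.76) and Tnnt2 (cardiac troponin T, 1.17) also rose, as did the channel-like Tmc3 (1.52), Fam196b (1.49), the cell-cycle arrest gene Rprm (1.42), the protease Adamts19 (1.40), the cadherin Pcdh20 (1.28) and Slitrk6 (1.14). The fitted falls of the synaptic organisers Cbln3 (-3.89, SE 1.18, adjusted p = 0.012, 0 of 8 mice below the wild-type median) and Cbln1 (-2.26, SE 0.732, adjusted p = 0.0179, 4 of 8) rested on wild-type male 2, at 60.7 and 34.7 CPM. Without that library the fits turned to 0.996 (adjusted p = 0.0153) and 0.0429 (adjusted p = 0.89), and without the 3 striatal libraries that stood apart (wild-type male 2 and male 3, and Polq+/- female 3) to 0.867 (adjusted p = 0.0445) and 0.0374 (adjusted p = 0.902). The proportion of rises depended on scaling: on the deposited FPKM, tested with limma trend, 5355 genes were higher and 1811 lower (74.7% higher against 52.7%).

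Other groups of genes moved in striatum of Q140 mice, where 32.1% of all tested genes were called. Clustered protocadherins, which give neurons their surface identity, rose in 33 and fell in 2 of 57 tested genes (40 and 0 on FPKM; 37 and 4 adjusted over the list alone), with Pcdhb3 at 0.98, Pcdhb19 at 0.80, Pcdhb9 at 0.72 and Pcdhb20 at 0.61. Their calls are uncertain gene by gene because the members are near-identical copies that share reads (camera adjusted p = 7.05e-10; adjusted p = 0.0651 with an estimated correlation). Wild-type male 3 stood 0.531 below the tissue mean of this list on the log2 scale (other wild types 0.046 to 0.212 below), and without it 32 rose and 7 fell (33 and 8 adjusted over the list alone; adjusted p = 0.0114 with an estimated correlation). Of 12 tested developmental transcription factors 4 rose and 1 fell, the same adjusted over the list alone, and without wild-type male 3 none fell (4 rises and 1 fall adjusted over the list alone). Wt1 had 16 counts summed over the 8 wild-type libraries and 482 over the 8 Q140 libraries, Onecut1 9 and 157, Hoxa7 12 and 97, and Sox11 4736 and 8269. The list was at camera adjusted p = 0.0152, and at adjusted p = 0.111 with an estimated correlation. Wt1, Onecut1 and Hoxa7 could pass the low-count filter only through the Q140 carriers. Members of the fixed list that stayed low were not tested, so its counts and camera's p lean towards rises. Activity-regulated immediate early genes fell in 9 of 20 (9 on FPKM; 10 adjusted over the list alone), including Egr2 (-1.86), Homer1 (-0.80), Egr1 (-0.67) and Egr3 (-0.64), with camera adjusted p = 0.00155 and adjusted p = 0.561 with an estimated correlation. Circadian clock genes fell in 9 of 12 (6 on FPKM; 9 adjusted over the list alone), among them Ciart (-0.70), Npas2 (-0.59), Dbp (-0.53) and Nr1d1 (-0.35), at camera adjusted p = 0.000212 and adjusted p = 0.0651 with an estimated correlation.

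Several marker lists of non-neuronal cells held members that fell by small amounts. Of all tested genes 32.1% were called in this comparison, rises and falls together, and oligodendrocyte and astrocyte markers were near that share. Microglial markers fell in 11 of 15 (4 on FPKM; 14 adjusted over the list alone), such as Cd68 (-0.19) and Cx3cr1 (-0.17), with camera adjusted p = 0.000212 and adjusted p = 0.175 with an estimated correlation. Endothelial markers fell in 7 of 10 (5 on FPKM; 7 adjusted over the list alone), among them the growth factor receptor Kdr (-0.39) and the cadherin Cdh5 (-0.23), with camera adjusted p = 0.0101 and adjusted p = 0.175 with an estimated correlation. Mural cell markers fell in 5 of 9 (2 on FPKM; 7 adjusted over the list alone), Tagln by most (-0.87), with camera adjusted p = 0.0106 and adjusted p = 0.111 with an estimated correlation. Oligodendrocyte markers fell in 5 of 15 (3 on FPKM; 5 adjusted over the list alone), with Ugt8a at -0.37, at camera adjusted p = 0.0417 and adjusted p = 0.793 with an estimated correlation. Camera did not call this list without wild-type male 3 (adjusted p = 0.164), and without the 3 libraries that stood apart 2 of 15 fell, also over the list alone (adjusted p = 0.395). Astrocyte markers fell in 5 of 15 on counts (1 fell and 1 rose on FPKM; 6 fell adjusted over the list alone) and did not stand apart as a list (camera adjusted p = 0.0815), and 0 of 8 reactive astrocyte genes were called by edgeR (adjusted p = 0.571 by camera). DNA mismatch repair genes rose in 7 of 15 (10 on FPKM; 7 adjusted over the list alone) by small steps, with Msh6 at 0.16, Mlh3 at 0.14 and Rfc1 at 0.12 (camera adjusted p = 0.026; adjusted p = 0.0651 with an estimated correlation). Of these 15 genes 5 rose without wild-type male 3 and 4 without the 3 libraries that stood apart, also over the list alone, where camera did not call the list without the 3 (adjusted p = 0.0556). Double-strand break repair genes, the process in which Polq itself acts, rose in 6 and fell in 3 of 18 (7 and 0 on FPKM; 6 and 3 adjusted over the list alone). The rises included Rbbp8 (0.60), the DNA-dependent kinase gene Prkdc (0.38), Xrcc5 (0.36) and Rad50 (0.20), and the list did not stand apart (camera adjusted p = 0.225).

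The same allele was then examined in mice labelled Polq+/-, in a comparison that shared no library with the first. Spiny neuron genes again fell, in 26 of 26 shared markers, 24 of 24 model-reduced genes and 4 of 6 indirect pathway markers (adjusted p = 0.0147, 0.00153 and 0.0304 with an estimated correlation, the last 0.0641 without wild-type male 3). Sfmbt2 (2.06), Tmc3 (1.55), Rprm (1.39), Ipcef1 (1.33), Lipg (1.29), Fam196b (1.27), Vwa5b2 (1.26), Tnnt2 (1.26), the stress-induced transcription factor Atf3 (1.17) and Ttn (1.15) had the largest rises among genes with an assigned name and a mean of at least 1 CPM. Below that level, Wt1 had 12 counts summed over the Polq+/- libraries and 535 over the Q140 Polq+/- libraries. Gpx6 (-2.67), Mafa (-2.38), Wnt8b (-2.33), Ddit4l (-2.17, SE 0.0709, adjusted p = 6.27e-22, 8 of 8), Sec14l3 (-1.82), Tmprss6 (-1.81), Cpne9 (-1.80) and the transporter Slc4a11 (-1.78) were among the largest falls. The fitted falls of Prlr (-2.13) and Tmem72 (-2.13) rested on striatum of Polq+/- female 3, whose choroid plexus markers stood 4.18 above the tissue mean on the log2 scale, and without it Prlr was fitted at -0.326 (adjusted p = 0.391; 7 of 8 mice below the Polq+/- median with all libraries) and Tmem72 at 0.0993 (adjusted p = 0.842). Circadian genes fell in 11 of 12 (adjusted p = 0.0304 with an estimated correlation), and protocadherins rose in 29 and fell in 4 of 57, or 34 and 6 adjusted over the list alone (adjusted p = 0.134 with an estimated correlation). Microglial markers fell in 1 of 15 (0 on FPKM and 0 adjusted over the list alone), with a median of -0.0894 against -0.158 in the first comparison, a difference that was not tested for the list (adjusted p = 0.66 with an estimated correlation). Endothelial markers fell in 6 of 10 (0 on FPKM; 7 adjusted over the list alone; adjusted p = 0.325 with an estimated correlation). In total 5741 genes passed, 31.4% of those tested, 2943 higher and 2798 lower (5530 and 1759 on FPKM), against 7308 at an unadjusted p under 0.05.

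Whether the number of Polq copies altered the response to Q140 was tested directly. No gene in striatum was called for a Q140 effect that differed with the Polq label. By edgeR 0 genes were called (smallest adjusted p = 0.996), with 893 at an unadjusted p under 0.05 where 914 would fall by chance. DESeq2, limma voom and limma trend on FPKM each called 0. The median SE of this test was 0.0859, against 0.0608 for Q140 against wild type, so small differences could be missed. The calls of the 2 Q140 comparisons shared 2165 rises, where 499 would be shared by independent lists of those sizes, and 2092 falls, where 425 would, and no gene was called in opposite directions. Over the 5869 genes called in Q140 against wild type, the fold changes in mice labelled Polq+/- had the same sign in 97.9% and a slope of 0.846 (r = 0.932, across genes, which are not independent replicates). Choosing the genes by the other comparison gave a slope of 0.985 over 5741 genes. Over all 18270 genes the sign agreed in 79.1%, with a slope of 0.777 (r = 0.786). With the axes exchanged the slopes were 0.795 over all genes and 1.03 over the 5869, so these slopes do not show a weaker effect in mice labelled Polq+/-. A Q140 signature score was also computed for each mouse from 200 genes chosen in the opposite sex. It was 0.757 higher in Q140 than in wild-type striatum (95% interval 0.716 to 0.8, exact two-sided permutation within sex p = 0.00041, the smallest these permutations can give). Between Q140 Polq+/- and Q140 it differed by -0.00614 (-0.0411 to 0.0285, exact permutation p = 0.75), or -0.811% of the Q140 effect (-5.25 to 3.87). The Q140 effect on the score in mice labelled Polq+/- was 0.78 (0.757 to 0.806, exact permutation p = 0.00041), and mice labelled Polq+/- without Q140 differed from wild type by -0.0294 (exact permutation p = 0.15).

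**Figure D2:**
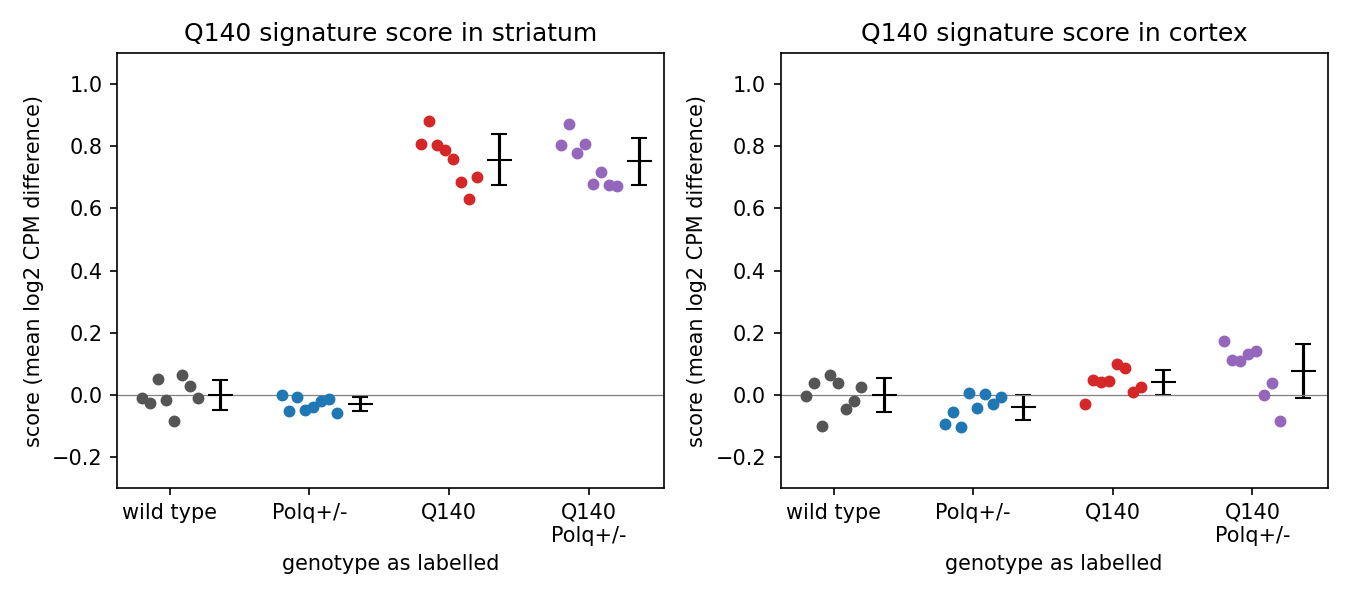
Q140 signature score (mean signed log2 CPM relative to the wild types of the same sex, y axis) for each mouse by labelled genotype (x axis), in striatum and cortex. Points are mice and the bar is the mean ± SD (n = 8); in striatum the means were 0.757 in Q140 and 0.751 in Q140 Polq+/-, against 0 in wild type and -0.0294 in Polq+/-.

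**Figure D3:**
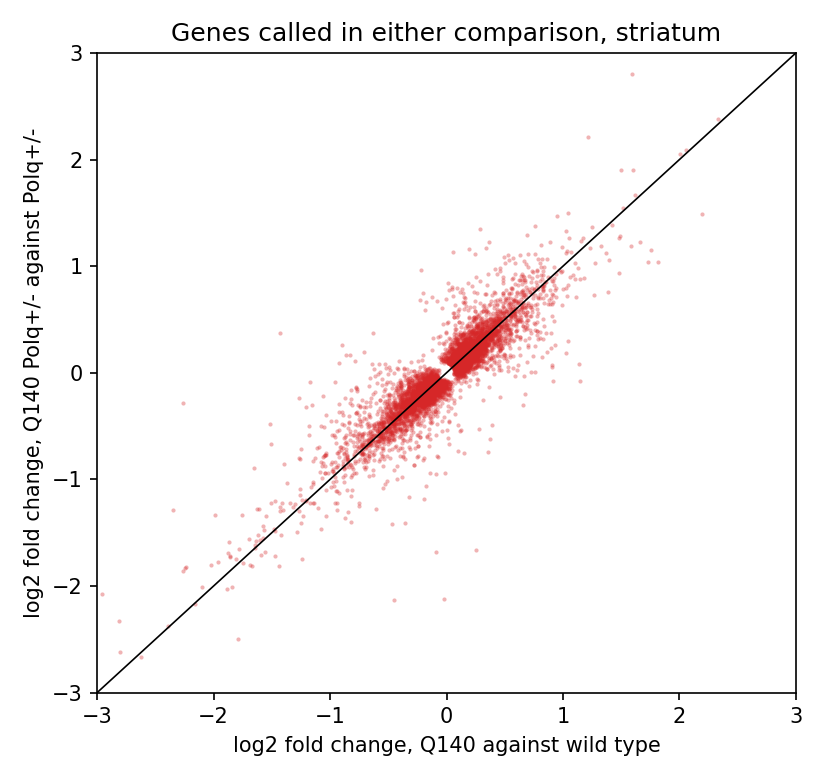
Log2 fold change of Q140 Polq+/- against Polq+/- (y axis) against that of Q140 against wild type (x axis) in striatum, for the 7353 genes called in at least 1 of the 2 comparisons. Each point is a gene, the diagonal marks equal effects, and 8 genes lie outside the axes, which end at ±3.

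The effect of the Polq label itself was small in striatum and lay on 1 chromosome. In mice labelled Polq+/- against wild type 9 of 18270 genes were called, 6 higher and 3 lower, with 924 at an unadjusted p under 0.05 where 914 would fall by chance. Fbxo40, a ubiquitin ligase adaptor gene beside Polq (36963460 to 36990467), went from 0.274 to 5.02 CPM (4.17, SE 0.248, adjusted p = 3.96e-13, 8 of 8 mice above the wild-type median). The myosin kinase gene Mylk (1.11), Ccdc80 (0.62), the "don't eat me" surface protein gene Cd47 (0.39) and the long non-coding RNA Dubr (0.27) also rose, and the axon guidance gene Sema5b (-0.46), the centrosomal Cep97 (-0.27) and Pcnp (-0.20) fell. Tmem45a2, under the abundance minimum for naming and named after its value was seen, went from 0.0681 to 0.284 CPM. All 9 lie on chromosome 16, which holds 2.92% of tested genes (Fisher's exact p = 1.43e-14), and 4 lie within the 10 Mb window around Polq fixed beforehand (Fisher's exact p = 3.39e-07). Camera called 9 of the fixed lists in this comparison, among them nuclear-encoded respiratory chain genes (adjusted p = 3.39e-09; adjusted p = 0.675 with an estimated correlation) and protocadherins (adjusted p = 6.09e-06; adjusted p = 0.537 with an estimated correlation), with no member called over all genes and each at 0.537 or more with an estimated correlation. Without wild-type male 3 camera called 4 lists, and these 2 were at adjusted p = 0.243 and 0.0489 (adjusted p = 0.955 and 0.631 with an estimated correlation). Without the 3 libraries that stood apart 4 genes were called, all of them rises. Tmem45a2 (1.86), Sema5b (-0.504), Cep97 (-0.284) and Pcnp (-0.177) were then at adjusted p = 0.0727 and Dubr (0.218) at adjusted p = 0.231. Sema5b, Dubr and Cep97 also missed the threshold without some single libraries.

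In mice labelled Q140 Polq+/- against Q140 10 genes were called in striatum, 5 higher and 5 lower (611 at an unadjusted p under 0.05). Fbxo40 (3.76, SE 0.232, adjusted p = 1.26e-12, 8 of 8), Mylk (1.35), Ccdc80 (0.68), Cd47 (0.38) and Tmem45a2 (1.57) rose. Sema5b (-0.60), Cep97 (-0.37), the sugar transporter Slc35a5 (-0.27), Pcnp (-0.23) and the immune-inhibitory ligand gene Cd200 (-0.19) fell. All 10 lie on chromosome 16 (Fisher's exact p = 4.11e-16), 6 of them within 10 Mb of Polq (p = 2.85e-11 by Fisher's exact test). With the comparison in mice without Q140, which shares no library, 5 rises and 3 falls were common. No gene of the spiny neuron lists was called, and among the lists camera called blood genes alone (adjusted p = 0.0152; adjusted p = 0.943 with an estimated correlation).

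**Figure D4:**
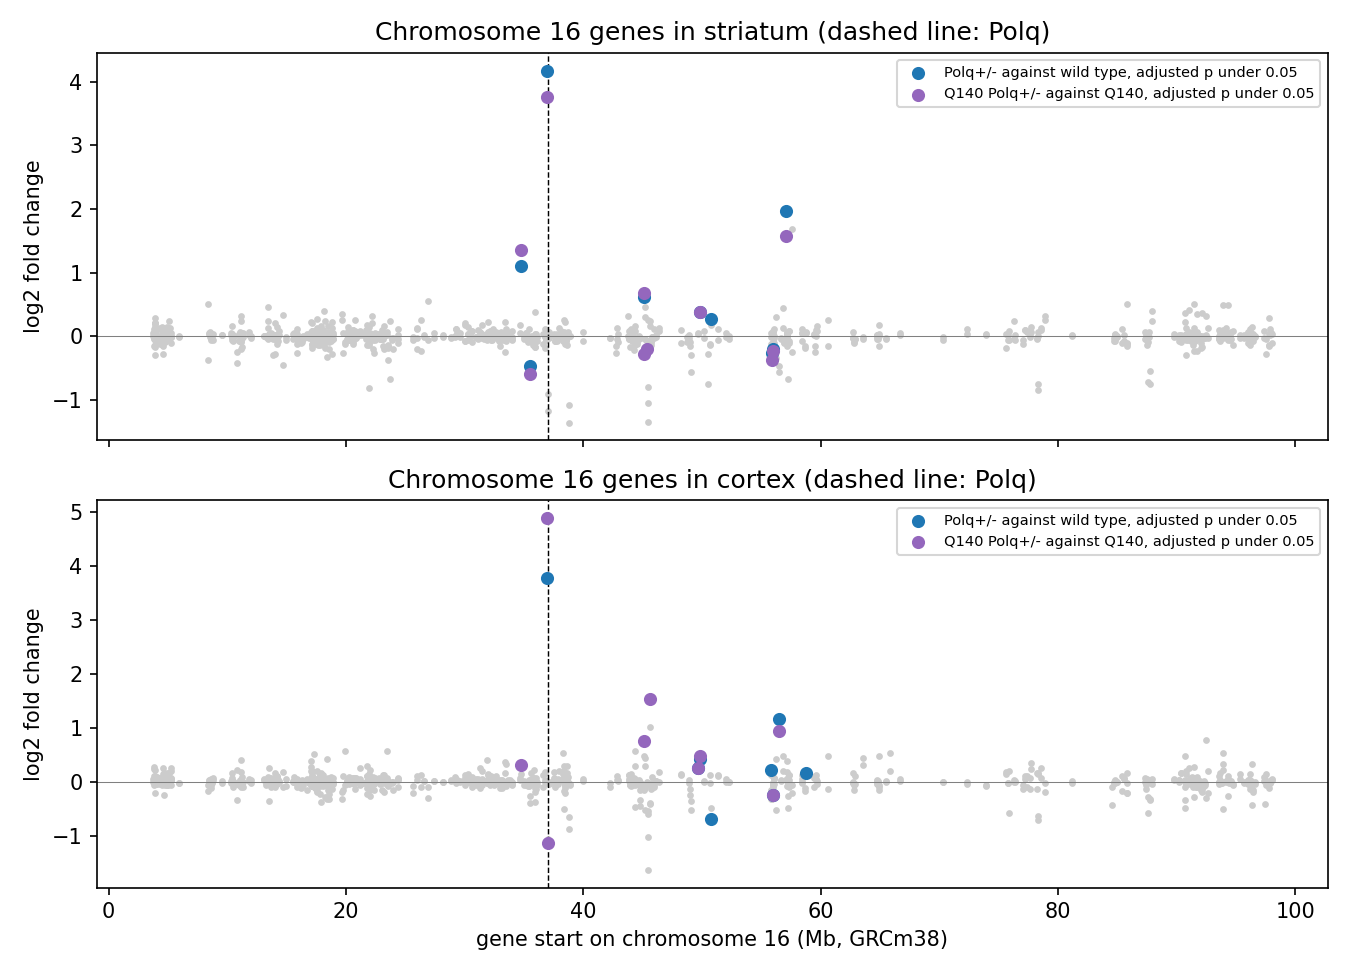
Log2 fold change (y axis) of tested chromosome 16 genes against gene start in Mb (x axis) for the 4 comparisons by Polq label. Coloured points are genes called at the adjusted threshold, grey points were not called and the dashed line marks Polq; the called genes other than Polq lie between 34745210 and 58734251.

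In cortex the Q140 allele moved few genes. Q140 against wild type called 63 of 18116 genes, 26 higher and 37 lower (34 and 24 on FPKM), with 1770 at an unadjusted p under 0.05 where 906 would fall by chance. Abhd1, a hydrolase gene on chromosome 5, rose from 2.6 ± 0.5 to 6.31 ± 0.544 CPM (1.28, SE 0.127, adjusted p = 1.61e-07, 8 of 8). The oligodendrocyte gene Enpp6 (0.76), Anln (0.52), the matrix genes Adamtsl1 (0.51) and Smoc1 (0.47), the choline dehydrogenase gene Chdh (0.47), the lipocalin Apod (0.40), Arhgap6 (0.36), Cgref1 (0.34) and the tetraspanin Cd82 (0.31) followed. Falls were led by the kinase-like Plk5 (-0.50), Agmat (-0.46), Ddit4l (-0.45), the orphan receptor Gpr153 (-0.42), Proser2 (-0.37), the protein-coding ENSMUSG00000110105 (-0.35) and Tmem91 (-0.32), with Camk2n1, an abundant inhibitor of CaM kinase II, going from 2910 to 2380 CPM (-0.29, SE 0.0386, adjusted p = 8.02e-05, 8 of 8), Susd5 (-0.26) and Atraid (-0.26). Model-reduced striatal genes fell in 3 of 24 (6 fell and 2 rose adjusted over the list alone), Ddit4l, Arpp21 (-0.17) and Rgs4 (-0.15), and the list was lower at camera adjusted p = 0.00834 and adjusted p = 0.0207 with an estimated correlation. Of the 63 genes 7 lay within 10 Mb of Htt (11.1% against 1.06% of tested genes, Fisher's exact p = 4.51e-06). Genotypes were unevenly spread over the plate columns, and with the column as a factor 25 genes were called, 21 of them among the 63. DESeq2 called 154 genes, a fit with a first surrogate variable 99 and an adjusted p under 0.1 gave 128. Without Q140 male 1 the count was 23 and without wild-type female 3 it was 39, and 10 of the 20 genes named here missed the threshold without at least 1 library.

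The Q140 allele was compared in cortex of mice labelled Polq+/- as well, where 61 genes were called, 22 higher and 39 lower (22 and 13 on FPKM; 1884 at an unadjusted p under 0.05). Abhd1 (1.13, SE 0.124, adjusted p = 1.07e-06, 8 of 8), Ttc34 (0.68), Enpp6 (0.60), Anln (0.50), Chdh (0.42), the DNA sensor gene Aim2 (0.41), Cgref1 (0.39), the mitochondrial ribosomal Mrpl33 (0.33), Tapbpl (0.27) and Arl4a (0.19) rose. The neuropeptide precursor Cartpt (-0.60), Gpr153 (-0.35), the myelination inhibitor Lingo1 (-0.27), the tetraspanin Tspan2 (-0.26), Acvrl1 (-0.25), Camk2n1 (-0.23), the semaphorin Sema7a (-0.22), Syt12 (-0.20), the glutamate receptor Grm4 (-0.19) and R3hdm1 (-0.17) fell. The cortical comparisons shared 10 rises (0.0316 for independent lists) and 11 falls (0.0797), and all 63 genes of the first had the same sign in the second, with a slope of 1.02 (r = 0.958, across genes). The slope rested on the predicted gene Gm2420 (3.26 and 4.04), whose level is uncertain, and without it was 0.731 (r = 0.941). Over all 18116 tested genes the sign agreed in 57.9%, with a slope of 0.17, or 0.189 with the axes exchanged (r = 0.179). The interaction called 0 genes by edgeR (smallest adjusted p = 0.99; 863 at an unadjusted p under 0.05), and 0 by DESeq2, limma voom and limma trend on FPKM. The cortical score differed by 0.0368 between Q140 Polq+/- and Q140 (-0.00993 to 0.087, exact permutation p = 0.29), and by 0.0413 between Q140 and wild type (exact permutation p = 0.11), so it did not separate these groups. Between Q140 Polq+/- and Polq+/- it differed by 0.118 (0.0716 to 0.166, exact permutation p = 0.0069). DESeq2 called 181 genes and an adjusted p under 0.1 gave 133, while fitting only the groups compared gave 34. With the plate column as a factor 35 genes were called, and without the 4 mice of low Polq 14, 13 of them among the 61. Leaving out any 1 library but Q140 Polq+/- female 2, female 3 or male 2 moved the count by over 1.5 times, to between 24 (without Polq+/- female 1) and 139 (without Q140 Polq+/- male 1).

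The Polq label in cortex again moved chromosome 16 genes. In mice labelled Polq+/- against wild type 8 genes were called, 6 higher and 2 lower (841 at an unadjusted p under 0.05). Fbxo40 (3.79, SE 0.264, adjusted p = 2.04e-10, 8 of 8), the matrix gene Abi3bp (1.17), Cd47 (0.43), the ciliary transport gene Ift57 (0.25), Nxpe3 (0.21) and Cldnd1 (0.16) rose, and Dubr (-0.68) and Pcnp (-0.24) fell. All 8 lie on chromosome 16 (Fisher's exact p = 5.18e-13), though 1 of the 8 lies within 10 Mb of Polq (p = 0.0589 by Fisher's exact test). Dubr moved in the opposite direction to striatum, where it rose by 0.27. In Q140 Polq+/- against Q140 10 genes were called, 8 higher and 2 lower (1136 at an unadjusted p under 0.05). Fbxo40 (4.89, SE 0.284, adjusted p = 1.71e-12, 8 of 8), BC016579 (1.53, under the abundance minimum and named after its value was seen), Abi3bp (0.94), Ccdc80 (0.75), Cd47 (0.48), Mylk (0.32), Gm7887 (0.28) and Ift57 (0.26) rose, and Polq itself (-1.14) and Pcnp (-0.24) fell. Gm7887, a processed pseudogene on chromosome 6 whose reads cannot be separated with certainty from those of its parent gene, was the 1 called gene off chromosome 16 (8 of 9 other than Polq on it, Fisher's exact p = 4.54e-12). Without Polq+/- female 1, female 2 or male 3, or wild-type female 3 or male 4, 5 genes were called in the first comparison, and without the 4 mice of low Polq 6 in the second, where DESeq2 called 16. Camera called 5 lists in the first comparison and 4 in the second, and their adjusted p were 0.384 or more with an estimated correlation.

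The Q140 effect was compared between the tissues of the same mice with the mouse as a block. It differed in 4025 of 19091 genes, 1960 more positive in striatum and 2065 more negative (6064 at an unadjusted p under 0.05). Sfmbt2 (difference 2.04, SE 0.129, adjusted p = 1.18e-15), Dsp (1.81), the germ line gene Tdrd5 (1.48), Fam196b (1.42), Rad51ap2 (1.39), Fbxo40 (1.39), Pcdh20 (1.30), Tnnt2 (1.20) and Ipcef1 (1.18) were among the largest positive differences. Tmem114 (-2.84), Mafa (-2.27), Serpinb1b (-2.14), Abhd11os (-1.95), Cpne9 (-1.87), Phex (-1.85) and Egr2 (-1.76) had large negative ones, and Gbx1 (-1.84) was at adjusted p = 0.0813 without the 3 mice whose striatal library stood apart. The minimum of 1 CPM for naming was taken over all 64 libraries, and Fbxo40 met it through the mice labelled Polq+/-. In wild-type striatum other than male 2, Fbxo40 lay at 0.164 to 0.47 CPM and Rad51ap2 at 0 to 0.138 CPM, so their differences rest on low counts. The fitted differences of Neurod1 (-5.00, SE 1.8) and Fat2 (-4.82, SE 1.67) rested on striatum of wild-type male 2, at 13.6 and 55.4 CPM against 0 to 0.0553 and 0 to 0.195 in the other wild types. Without the 3 mice they were 0.129 (SE 0.724, adjusted p = 0.934) and -1.08 (SE 0.895, adjusted p = 0.45). Of the 63 cortical genes 41 were also called in striatum, 38 in the same direction and 3 in the opposite one, where 20.6 would be for independent lists, and 36 of the 63 had a Q140 effect that differed between tissues. Over 17422 genes tested in both tissues the fold changes had r = 0.18 (across genes).

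The Q140 effect was also compared between the sexes. In striatum it differed in 5 genes, all with a more negative effect in females. Protocadherin Pcdh11x on the X chromosome (difference -0.71, SE 0.111, adjusted p = 0.00352) went from 36.4 to 38.1 CPM in females and from 28 to 48 CPM in males (means of 4 mice), and the guanylate cyclase subunit Gucy1a3 (-0.33) from 206 to 183 CPM and from 182 to 203 CPM. The others were Nucb2 (-0.43), Tmem196 (-0.82) and 1110015O18Rik (-1.36). Without the 3 libraries that stood apart 3 genes were called. Pcdh11x (-0.754) and 1110015O18Rik (-1.43) kept their call (adjusted p = 0.0338), and Gucy1a3 (-0.33, adjusted p = 0.172), Nucb2 (-0.407, adjusted p = 0.185) and Tmem196 (-0.729, adjusted p = 0.255) lost it. DESeq2 called 38 genes, 7 with a more positive effect in females and 31 with a more negative one. In cortex 1 gene differed, Gm17281 (-1.69, SE 0.269, adjusted p = 0.00537), under the abundance minimum for naming and named after its value was seen. DESeq2 called 36 cortical genes, a fit without the low-count filter 6 and an adjusted p under 0.1 gave 8. At an unadjusted p under 0.05 there were 1990 genes in striatum and 1984 in cortex, where 914 and 906 would fall by chance.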

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

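The tests of chromosome 16 and of the genes near Htt, the count of the lowest Polq mice shared between tissues and the comparison of Abhd1 between tissues were chosen after the results were seen. The splits of the mice were not. The test of mislabelled mice was framed after the Polq levels and the called genes were seen, and only its prediction was written before its own value.

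The genes that followed the Polq label clustered on chromosome 16. Of 17 distinct called genes other than Polq in the 4 comparisons, 94.1% lie there, against 2.88% of tested genes (Fisher's exact p = 3.07e-24). That 1 lies elsewhere argues against loss of Polq acting strongly on many genes across the genome. Effects too small to be called are not covered, and the gene tests of the Polq label were not simulated. Reads lost to variants against the reference would lower counts, so the called rises go against it for the rising genes. These rises numbered 24 on chromosome 16, summed over the 4 comparisons, with a gene counted again in each. All were over 2 standard errors, which being called already requires, so that limit adds no further evidence. For the falling genes, the fall differed between tissues by 6.81 standard errors for Dubr and by over 3 for Cd200 as well. The other 4 (Sema5b, Cep97, Pcnp and Slc35a5) were within 3. The tissues were taken as independent although they share mice, and the genes were picked for a call in at least 1 tissue. That lost reads lower a gene alike in both tissues was assumed and not tested. Dubr's striatal rise was at adjusted p = 0.231 by edgeR without the 3 striatal libraries that stood apart. The difference therefore argues against lost reads for Dubr and Cd200 but does not exclude them. A bound on the size of the fall, put in place of this comparison after the values were known, excluded nothing, since the largest fall, -0.683, is smaller than losing 1 of 2 alleles allows. Donor sequence carried with the targeted allele may account for the cluster, which stays a hypothesis, and effects of the targeting itself on neighbours such as Fbxo40 stay open.

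Of the 63 cortical genes called for Q140, 7 lie within 10 Mb of Htt (Abhd1, Slc5a6, Atraid, Cgref1, Dpysl5, Gm2420 and Mrpl33), and 5 of the 7 were called in striatum in the same direction, as were 33 of the other 56 cortical calls (Fisher's exact p = 0.693), so this agreement does not favour donor sequence around the knock-in allele over an effect of the repeat. Of the cortical calls 11.1% lie in this window, so most of them are not neighbours of Htt within it. Flanking sequence that reaches beyond 10 Mb or acts on genes elsewhere was not tested, so it cannot be excluded as the whole cause. Abhd1 in cortex of Polq+/- female 4 was 6.1 CPM, against 2.22 to 2.91 CPM in the 7 other mice of that genotype, and in striatum of the same mouse it was 7.39 CPM against 3.72 to 4.3, levels like those of Q140 carriers (means 6.31 and 7.57 CPM), while its striatal signature score was -0.049. Donor sequence apart from the expanded repeat may set Abhd1 in this mouse, as a hypothesis; a direct effect of the repeat on the other genes near Htt stays open. Gm2420, a predicted gene, is uncertain because its reads may be shared with a copy.

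Polq itself was far lower in 4 of the 16 mice labelled Polq+/- than in the other 12. Counting noise or a failed library is excluded, since all 4 of the lowest mice in striatum were the 4 lowest in cortex, where another library was made (chance of all 4 shared 0.00055). Mislabelled mice that carry no intact Polq copy may account for it: of the 4, 3 were among the 4 of 16 with the largest shift of the other chromosome 16 genes in each tissue, the least the test asked for, and all 4 had the highest Fbxo40 of the 16 in both tissues. The test is not independent. The genes lie on the same chromosome as Polq, and they and their signs came from comparisons that include these 4 mice, which favours a large shift in them. It therefore cannot decide whether the labels are wrong. The labels were kept, and no biological explanation was tested.

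Splits of the same mice within sex into other groups (within genotype for the sex difference, and within Q140 status as well for the interaction) were counted with the real one included, 100 per result and 24 for the difference between tissues, where each fit took longer. In striatum, chance can be excluded for Q140 against wild type (1 of 100 splits; 5869 genes, highest other 3825), Polq+/- against wild type (1; 9 genes, highest other 4), Q140 Polq+/- against Q140 (1; 10 genes, highest other 0) and Q140 Polq+/- against Polq+/- (1; 5741 genes, highest other 2913). In cortex it can be excluded for Q140 against wild type (1 of 100, 63 genes, highest other 15) and Polq+/- against wild type (1, 8 genes, highest other 3). The same holds there for Q140 Polq+/- against Q140 (1, 10 genes, highest other 2). For cortical Q140 Polq+/- against Polq+/- 2 of 100 splits called as many as the real 61 genes, but another split called 91. Leaving out 1 library moved that count to between 24 and 139, so chance is excluded there by the count of splits alone. For the difference of the Q140 effect between tissues chance can be excluded too (1 of 24, 4025 genes, highest other 1684). For the 5 genes whose Q140 effect differed between sexes in striatum, 3 of 100 splits called as many. These splits mixed females and males within a genotype, so differences between the sexes entered the spread within groups. They therefore cannot decide whether chance gave the 5 genes. The highest other split called 37 genes, several times as many, and the reason was not tested. For the 1 such gene in cortex, Gm17281, chance could not be excluded (5 of 100; highest other 1). The interaction called 0 genes in each tissue, which all 100 splits reach by definition, and the highest other count was 1 in striatum and 1 in cortex.

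Within a group of 8 mice, 9 of 68 combinations of named gene or signature score, genotype and tissue had 1 mouse far from the rest. Chance gives 3.4, about 1 in 20, for items not chosen by their values. Genes other than Polq and Htt were chosen for the largest changes, and Cbln3 was named through wild-type male 2. The count can therefore not be judged against chance. Besides Abhd1, Htt was 137 CPM in striatum of wild-type male 3 (others 209 to 220), a library that stood 0.304 above the tissue mean of ribosomal protein genes on the log2 scale and 0.251 above that of nuclear respiratory chain genes, and Cbln3 was 60.7 CPM in wild-type male 2 (others 0.0821 to 0.331). Sfmbt2 was 2.89 CPM in striatum of Polq+/- male 2 (others 2.05 to 2.4). In Polq+/- male 3, Fbxo40 was 8.52 CPM (others 3.92 to 5.47) and Sema5b 17.5 CPM (others 23.4 to 25.8) in striatum, and Polq 0.602 CPM (others 1.2 to 1.38) in cortex. Plk5 was 39.1 CPM in cortex of wild-type female 2 (others 23.1 to 28.4) and Dubr 5.99 CPM in cortex of Q140 female 2 (others 4.3 to 5.1). Tests of the difference itself found that the Q140 effect differed between tissues in 4025 genes, between sexes in 5 genes in striatum and in 1 in cortex.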

How the results depend on the processing

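The settings that leave out the 4 mice of low Polq or the 3 striatal libraries that stood apart, gene lists without wild-type male 3 and the concordance without Gm2420 were chosen after seeing the data; all others were planned. The interaction of Q140 and the Polq label stayed at 0 genes in both tissues under every alternative run, and the striatal Q140 counts stayed within 1.5 times. Leaving out 1 library at a time gave 5511 to 6202 genes for striatal Q140 against wild type, 6 to 10 for Polq+/- against wild type, 9 to 11 for Q140 Polq+/- against Q140, 5396 to 5644 for Q140 Polq+/- against Polq+/- and 0 to 0 for the interaction. In cortex these ranges were 23 to 82, 5 to 10, 8 to 11, 24 to 139 and 0 to 0. The score difference between Q140 Polq+/- and Q140 ranged from -0.0244 to 0.0117 in striatum and from 0.023 to 0.0599 in cortex. DESeq2 called 154 genes for cortical Q140 against wild type, 16 for Q140 Polq+/- against Q140, 181 for Q140 Polq+/- against Polq+/-, and 38 (striatum) and 36 (cortex) for the difference between sexes. The plate column gave 25 and 35 cortical genes for the Q140 comparisons, a first surrogate variable 99 for Q140 against wild type, and an adjusted p under 0.1 gave 128, 133 and, for the sex difference in cortex, 8; without the low-count filter the last was 6. For cortical Q140 Polq+/- against Polq+/-, FPKM gave 35 and 34 genes with pseudocounts of 0.1 and 1, fitting only its groups 34, and leaving out the 4 mice of low Polq 14, while Q140 Polq+/- against Q140 fell to 6. Without the 3 libraries that stood apart, Polq+/- against wild type in striatum called 4 genes and the sex difference 3. Of 55 list calls by camera, 8 held with an estimated correlation, and fry called 31 by direction. The concordance slopes were 0.985 in striatum and 1.16 in cortex when genes were chosen by the other comparison, and 0.731 in cortex without Gm2420. Apart from settings that test fewer samples, the cause was not tested. For named genes, planned settings kept 1576 results on the same side, made 138 weaker and 10 stronger, and reversed 0; leaving out 1 library kept 1978, made 210 weaker, 1 stronger (Htt in striatum of Q140 against wild type, -0.118 without wild-type male 3) and reversed 3. The reversed ones were Cbln3 (striatum, Q140 against wild type) at 0.996 and Cbln1 (striatum, Q140 against wild type) at 0.0429 without wild-type male 2, and Tmem72 (striatum, Q140 Polq+/- against Polq+/-) at 0.0993 without Polq+/- female 3. Their log2 fold changes with 1 library left out ranged from -4.13 to 0.996, from -2.45 to 0.0429 and from -2.34 to 0.0993, and without all 3 libraries they were 0.867, 0.0374 and 0.101. Same-numbered mice correlated little, with a median r of 0.0111 in striatum and 0.0179 in cortex, against -0.00344 and -0.0081 for other numbers. In each tissue 13 of 32 mice fitted best with their own number, a count not set against chance. Mice sharing a name prefix had a median r of 0.022 and 0.0599, against -0.00156 and -0.00543 for other prefixes, so shared structure is not ruled out. The replicate block in place of sex called 5878, 9, 11, 5738 and 0 genes in striatum and 74, 8, 11, 70 and 0 in cortex. Depth limits the named genes of low level, above all Polq at 6 to 148 counts per striatal library.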

Other observations

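The gene lists and tests of this part were fixed before the data were examined, and the fits without wild-type male 3 or the 3 libraries that stood apart were chosen after list levels were seen. In striatum of Q140 mice against wild type, some markers of neurons outside the spiny class moved in single genes while their lists did not stand apart by camera. Of all tested genes 32.1% were called in this comparison, and the lists of this paragraph were near or below that share. Of 12 cortical excitatory markers 3 rose and 1 fell (3 and 1 on FPKM and adjusted over the list alone), Cux2 (0.40) and Mef2c (0.15) among the rises against Nptxr (-0.35), with camera adjusted p = 0.596 upward although the list's mean and median were below 0 (-0.0437 and -0.0285). Of 10 thalamic and pallidal markers Tnnt1 (-1.18) and Calb2 (-0.92) fell and Rora (0.17) rose (adjusted p = 0.433), and wild-type male 2 stood 0.776 above the tissue mean of this list and 0.806 above that of the cortical list on the log2 scale. Of 13 interneuron markers 1 fell (Kit, -0.12; 0 on FPKM; adjusted p = 0.393), and of 10 oligodendrocyte precursor markers Tnr (0.23) and Lhfpl3 (0.21) rose and C1ql1 (-0.22) fell (4 rises and 0 falls on FPKM; adjusted p = 0.596). Adjusted over the list alone these 3 lists had the same counts. Choroid plexus (8 genes, adjusted p = 0.86) and blood genes (5 genes, adjusted p = 0.596) had 0 members called by edgeR over all genes or over the list alone (2 choroid plexus genes rose without the 3 libraries that stood apart), and Ttr, the main choroid plexus transcript, stood at 1240 CPM in Polq+/- female 3.

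Metabolic and stress genes of the same comparison went in mixed directions. Among these lists, p53 targets alone were called in a larger share on counts than the 32.1% of all tested genes. Cholesterol synthesis genes fell in 3 of 20, the methyl sterol oxidase Msmo1 (-0.32), the regulator Srebf2 (-0.16) and Insig1 (-0.16), and rose in 2, Mvk at 0.19 among them (2 falls and 5 rises on FPKM; the counts were the same adjusted over the list alone; adjusted p = 0.933). Nuclear-encoded respiratory chain genes fell in 11 and rose in 4 of 75 on counts and in 1 and 18 on FPKM, so that their direction turned with the scaling (9 and 4 adjusted over the list alone; adjusted p = 0.394), with Ndufs3 at -0.26 and Atp5g1 at 0.28. Wild-type male 3 stood 0.251 above the tissue mean of this list on the log2 scale (other wild types -0.0657 to 0.0189), and in Q140 Polq+/- against Polq+/- 16 of the genes rose and 3 fell on counts (16 and 1 adjusted over the list alone; 38 and 1 on FPKM; camera adjusted p = 0.0883). Without wild-type male 3, 8 fell and 15 rose in Q140 against wild type (8 and 14 adjusted over the list alone; adjusted p = 0.438). Mitochondrially encoded genes fell in 2 of 13, mt-Nd2 (-0.16) and mt-Nd1 (-0.14), on counts and over the list alone, with 1 fall and 1 rise on FPKM (adjusted p = 0.307). Ribosomal protein genes fell in 5 and rose in 1 of 75 on counts and in 3 and 4 on FPKM (3 and 1 adjusted over the list alone; adjusted p = 0.0516), the largest fall that of Rpl31 (-0.35). Wild-type male 3 stood 0.304 above the tissue mean of this list (other wild types -0.0941 to 0.0686), and without it 3 fell and 4 rose (2 and 1 adjusted over the list alone; adjusted p = 0.718). Of 15 p53 targets 3 fell and 5 rose (3 and 6 on FPKM; 4 and 5 adjusted over the list alone; adjusted p = 0.933), with Gadd45a at -0.85, Plk2 at -0.31, Trp53inp1 at 0.24 and Mdm2 at 0.13. Heat shock genes had 1 fall, Hspe1 (-0.14), and 1 rise, Hspa8 (0.15), of 10 (0 and 1 on FPKM; adjusted p = 0.933; the counts were the same adjusted over the list alone), and interferon response genes 1 fall, Isg15 (-0.50), and 1 rise of 14 (0 and 1 adjusted over the list alone; adjusted p = 0.261).

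In cortex of Q140 mice, camera called astrocyte markers lower (adjusted p = 0.0177; adjusted p = 0.724 with an estimated correlation), mitochondrially encoded genes lower (adjusted p = 0.00834; adjusted p = 0.603 with an estimated correlation) and blood genes higher (adjusted p = 0.0092; adjusted p = 0.603 with an estimated correlation), each with 0 members called by edgeR over all genes. Globin genes are near-identical copies and their counts are uncertain.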
